A study of Mus musculus with 6 samples.

How the data were processed

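The deposited table holds 1 value for each of 45101 probe sets on 6 Affymetrix arrays, 2 each of GM-MPP, GM-DC and GM-TNFa-DC. Per the labels' protocols, total RNA was extracted with a column kit and DNase digestion, its quality was checked on a Bioanalyzer, and 1 microgram was labelled with a one-cycle kit. Per the submitters' processing notes the values were made with RMA, which corrects background, quantile-normalizes the arrays and summarises the probes of a probe set, and per the labels with Bioconductor. The version, the probe set definitions and which arrays were normalized together are not given in the sources used here. The log2 scale of the deposited values was inferred from their range of 1.89 to 14.4, which is the scale RMA gives; a quantile normalization removes differences in overall brightness between arrays. No detection call was used, so a dim gene's level is partly background and its change is compressed.

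Probe sets were named through the platform's annotation table, updated through Entrez identifiers to the symbols of a RefSeq table of assembly GRCm38.p6, of which no coordinates were used. Of the 45101 probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none listed. For 34741 of those with 1 symbol the Entrez identifier was in the RefSeq table. A gene was represented by the single-symbol probe set with the highest mean over all 6 arrays, which gave 18193 genes, 9010 of them with over 1 probe set. The genes of 25 lists came from textbook knowledge of blood cell development and dendritic cells, and 41 of 551 entries had no single-gene probe set.

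Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 3 groups sharing 1 estimate of the spread, 3 residual degrees of freedom), with Benjamini-Hochberg adjustment over the 18193 genes and a threshold of 0.05. Errors after ± are moderated standard errors of log2 changes, or SDs over the 2 arrays of a group where SD is written. Lists were tested with camera at a preset correlation of 0.01, adjusted over all 75 pairs of list and comparison. Camera called 45 of the 75 pairs, camera with an estimated correlation called 0 (lowest adjusted p = 0.351), and fry called 13, of which 12 were also called by camera at the preset correlation. With an estimated correlation camera has only the 3 residual degrees of freedom, so it can hardly call any list here. For erythroid and megakaryocyte markers in GM-DC against GM-MPP the estimated correlation was 0.0064, below the preset. Their camera adjusted p still went from 0.0205 to 0.465. For the NF-kB list the estimate was 0.159, above the preset. A call lost this way does not by itself show that correlated genes made it. Among the highest estimates were those of cell cycle (0.965), cholesterol synthesis (0.664), ribosome biogenesis (0.578) and MHC class II genes (0.482). For such lists the preset leaves out most of the estimated correlation, so their adjusted p at the preset is too low. Members were also adjusted over the list alone. Overlaps were set against independent lists and 100 simulations. Python 3.11.15 prepared the tables and matplotlib 3.10.9 drew the plots.

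The tests, alternatives, lists and the rule for named genes were fixed before the data were examined. Named were, per comparison, the 6 largest increases and 6 largest decreases among called genes whose arrays did not overlap, up to 3 called members of each list with the largest absolute change, and a panel of 21 genes whatever their result. Where no gene was called, genes were taken by absolute change among those without overlap. The text gives part of the genes so named. Alternatives were a second quantile normalization, median centring, leaving out dim genes, the mean of a gene's probe sets, all 45037 probe sets that are not controls, priors without trend or with a robust fit, only the 4 arrays compared, the replicate number as a block, each array left out, a 2-fold minimum, and camera with an estimated correlation and fry for lists. Values within each array number, the block on 4 arrays, simulations in which same-numbered dendritic cell arrays deviate together at the measured correlation of 0.806, and a test of the array number on the 4 dendritic cell arrays were added after seeing the data.

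The fit was tested on simulated arrays of 18193 genes with the means and spreads of the real ones, no batch, and 200 changed genes. The 24 measured NF-kB genes were also raised 2-fold and are not among the 200. For GM-DC against GM-MPP, 32% of genes changed 2-fold, 82% changed 4-fold and 96% changed 16-fold were called, with 9 unchanged genes called. For GM-TNFa-DC against GM-DC, 34%, 86% and 98% were called, with 15 unchanged genes called. Part of the changed genes were moved 16-fold or 64-fold, which eases the adjusted threshold for the others. Same-numbered arrays did not deviate together in these simulations.

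RNA quality was checked on control probe sets against both ends of a transcript, of which Gapdh and Actb were the brightest. The 3' minus 5' log2 difference lay between -0.003 and 0.184 for Gapdh and between 0.465 and 0.764 for Actb. For the dimmer controls it lay between -0.311 and 0.379 for Pcx, and for Tfrc at 1.761 and 1.976 on the GM-MPP arrays against 1.051 to 1.244 on the dendritic cell arrays. The Tfrc 5' probe set lay at 3.234 to 3.482 on the dendritic cell arrays, near their lower quartiles, so that difference is compressed. No array was left out of the main comparisons. Groups of 2 are too small for a test of outlying samples or for other splits of the samples. Probe sets with several or no listed genes entered only the alternative without collapsing.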

Results

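Gene expression was measured with Affymetrix arrays, which carry 45101 sets of short oligonucleotide probes, most of them against mouse transcripts. RNA came from cells grown out of the bone marrow of C57BL/6 mice. The 6 arrays fell into 3 groups of 2. GM-MPP are multipotent progenitors, cells that can still give rise to several blood lineages, grown with stem cell cytokines plus the growth factor GM-CSF. GM-DC are dendritic cells, the antigen-presenting cells of the immune system, obtained from such progenitors with GM-CSF. GM-TNFa-DC were obtained with GM-CSF plus TNFa, an inflammatory cytokine. The labels do not say whether the 2 arrays of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. Values were log2 expression levels with array medians between 4.67 and 4.77, and the number of arrays limits the precision. A gene near the array median lies close to the background of such arrays, so a fold change against it is not exact.

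Along the first principal component, which held 63.36% of the variance, the progenitors stood apart from both kinds of dendritic cell. The second, with 25.15%, parted the number-1 from the number-2 arrays of the dendritic cell groups. Over all probe sets, which are not independent replicates, GM-DC 1 correlated with GM-TNFa-DC 1 at r = 0.9876 and GM-DC 2 with GM-TNFa-DC 2 at r = 0.9902, above the 0.9696 between the GM-DC arrays. The GM-TNFa-DC arrays correlated at 0.9607 and the GM-MPP arrays at 0.9876. Poly-A control transcripts, which are added before labelling, were brighter on the number-1 array in 24 of 24 probe sets of each group, by 2.39-fold in GM-MPP, 2.16-fold in GM-DC and 2.60-fold in GM-TNFa-DC. Controls added at hybridisation differed by 1.03-fold, 1.07-fold and 0.865-fold. The model behind the main counts has no term for the array number. Because of these splits, values within each number and with the number as a block are given beside the pooled ones.

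**Figure D1:**
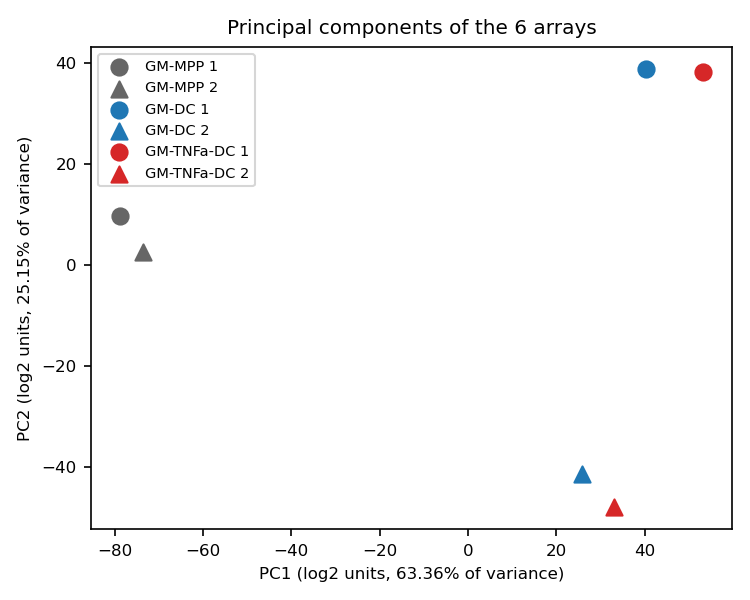
Principal components of the 6 arrays over 18193 genes, with component 1 (63.36% of variance) on the x axis and component 2 (25.15%) on the y axis, both in log2 units. Colours mark groups, and circles and triangles mark arrays 1 and 2. The GM-MPP arrays lie at the left, and the dendritic cell arrays at the right split by array number.

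The comparison of GM-DC with GM-MPP addresses which genes differ between the progenitors and the dendritic cells obtained from them. GM-DC had 340 genes higher and 479 lower of 18193 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The largest increases were in Mmp12, a macrophage elastase (log2 change 9.66 ± 0.35 SE), Car4, a membrane carbonic anhydrase (7.62 ± 1.08), the chemokines Ccl17 (7.20 ± 0.42) and Ccl5 (6.98 ± 0.72), the actin-bundling protein Fscn1 (6.84 ± 1.14) and the chemokine receptor Ccr7 (6.76 ± 0.70). Ccr7 guides dendritic cells to lymph nodes. The largest decreases were in the granule proteins Mpo (-7.94 ± 0.55), Ctsg (-7.13 ± 0.55), Elane (-6.35 ± 0.31) and Prtn3 (-6.09 ± 0.40), in Ms4a3 (-6.97 ± 0.50) and in Myb, a transcription factor of progenitors (-6.42 ± 0.52). Adjusted p for these 12 genes lay between 0.00213 and 0.0365, and each changed the same way on both array numbers.

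Of 18 measured neutrophil granule and lineage genes, 9 fell and none rose, or 15 adjusted over the list alone, and the list's median log2 change was -4.00. Mpo went from 12.44 ± 0.85 (SD, n = 2) to 4.51 ± 0.66. The list was called by camera (adjusted p = 1.17e-12, but adjusted p = 0.351 with an estimated correlation), with medians of -3.05 on the number-1 and -5.45 on the number-2 arrays. Of 22 stem and progenitor genes, 8 fell, or 11 lower and 1 higher adjusted over the list alone. Besides Myb they included Gfi1 (-5.03 ± 0.63), Hoxa9 (-4.12 ± 0.28), Cd34 (-3.81 ± 0.29, adjusted p = 0.00541) and the cytokine receptor Flt3 (-1.98 ± 0.36, adjusted p = 0.0443). The median was -0.77 (camera adjusted p = 2.65e-05, adjusted p = 0.458 with an estimated correlation), at -0.59 and -1.35 on numbers 1 and 2. Kit, the receptor for stem cell factor, did not pass (adjusted p = 0.960): it was at 7.09 and 7.22 in GM-MPP 1 and 2, but at 8.997 in GM-DC 1 and 5.65 in GM-DC 2.

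All 20 ribosome biogenesis genes were lower on both numbers, and 8 fell past the threshold, or 17 adjusted over the list alone, among them Dkc1 (-3.26 ± 0.37), Nop58 (-2.86 ± 0.44) and Nolc1 (-2.37 ± 0.37). Their median was -1.30 (camera adjusted p = 3.54e-12, adjusted p = 0.465 with an estimated correlation), at -1.10 and -1.47 on numbers 1 and 2. Of 29 cell cycle genes, only Mcm7, part of the replicative helicase, fell past the threshold (-2.36 ± 0.43), and 0 did adjusted over the list alone. The list's median of -1.99 (camera adjusted p = 8.67e-10, adjusted p = 0.491 with an estimated correlation) was -3.13 on number 1 and -0.84 on number 2. The estimated correlation of 0.965 lay far above the preset, so the list's adjusted p at the preset is too low. Mki67, a marker of dividing cells, had a change of -1.93 ± 0.60 and did not pass (adjusted p = 0.145). Of 17 cholesterol synthesis genes 1 fell, over all genes and adjusted over the list alone. It was Fdps (-3.34 ± 0.34), of whose 2 probe sets only 1 was lower. The median was -0.91 (camera adjusted p = 2.65e-05, adjusted p = 0.491 with an estimated correlation), at -1.41 and -0.61.

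All 14 measured genes of MHC class II presentation, which shows peptides to CD4 T cells, were higher on both numbers, and 5 rose past the threshold, or 10 adjusted over the list alone. H2-Aa went from 6.97 ± 0.31 to 12.86 ± 1.04 (SD, n = 2), a 59.1-fold rise, H2-Eb1 rose by 5.67 ± 1.07, H2-Ab1 by 5.46 ± 0.90, and Cd74, the invariant chain, by 4.66 ± 0.84 (adjusted p = 0.0445). The H2-Aa level in GM-DC was close to the brightest values of those arrays (14.2 and 14.4), where differences are compressed. Its fold is thus not exact. The median of 3.17 (camera adjusted p = 3.67e-08, adjusted p = 0.465 with an estimated correlation) was 3.94 on number 1 and 1.56 on number 2. Of 24 dendritic cell maturation genes 10 rose, or 17 adjusted over the list alone, including Ccl17, Ccl5, Fscn1, Ccr7 and Cd83 (5.28 ± 0.93). Their median was 2.12 (camera adjusted p = 4.90e-12, adjusted p = 0.351 with an estimated correlation), at 2.44 and 2.02. The costimulatory gene Cd80 rose by 1.76 ± 0.28 (adjusted p = 0.0321, 3 of its 4 probe sets higher). Cd86 (2.03 ± 0.46, adjusted p = 0.0750) and Cd40 (0.93 ± 0.87, adjusted p = 0.598) did not pass.

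Among 21 dendritic cell identity genes 5 rose, or 6 higher and 1 lower adjusted over the list alone. They included Itgax, which encodes CD11c (6.66 ± 0.34, adjusted p = 0.00219), the lectin Mgl2 (6.08 ± 0.78) and the transcription factor Irf4 (4.45 ± 0.62, adjusted p = 0.0248). The median was 1.00 (camera adjusted p = 0.00120, adjusted p = 0.475 with an estimated correlation), at 1.07 and 0.49. Irf8 (3.11 ± 0.69, adjusted p = 0.0705), Zbtb46 (1.61 ± 0.76, adjusted p = 0.299) and Id2 (0.76 ± 0.24, adjusted p = 0.152) did not pass. Of 25 transcription factors of dendritic cell development, 1 rose and 1 fell, Irf4 and Gfi1, or 2 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.456).

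Lysosome genes rose in 8 of 25 cases, or 16 adjusted over the list alone, with the proton pump subunit Atp6v0d2 (5.63 ± 0.47) and the cathepsins Ctsh (2.40 ± 0.35) and Ctss (2.37 ± 0.26). Their median was 0.97 (camera adjusted p = 1.37e-11, adjusted p = 0.351 with an estimated correlation), at 0.79 and 1.15. Of 26 pattern recognition and uptake receptors 5 rose, or 6 higher and 1 lower adjusted over the list alone, with Cd36 (6.34 ± 1.10), the beta-glucan receptor Clec7a (5.92 ± 0.22) and Clec4n (3.90 ± 0.20). That list had a camera adjusted p of 0.00409 (adjusted p = 0.601 with an estimated correlation, and 0.0608 without GM-DC 2) and medians of 0.50 and 0.64. Of 15 glycolysis genes 3 rose, or 7 adjusted over the list alone: Aldoc (3.15 ± 0.48), the glucose transporter Slc2a1 (2.38 ± 0.37) and Hk2 (1.28 ± 0.24). Their camera adjusted p was 0.00133 (adjusted p = 0.491 with an estimated correlation), and their medians were 0.35 and 1.10.

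Of 32 chemokines and cytokines 5 rose, or 6 adjusted over the list alone, among them Ccl17, Ccl5 and Ccl22 (5.44 ± 0.53). The median of 1.19 (camera adjusted p = 2.64e-06, adjusted p = 0.466 with an estimated correlation) was 0.47 on number 1 and 1.88 on number 2. Of 25 interferon-stimulated genes 4 rose, or 6 adjusted over the list alone, with Gbp2 (4.01 ± 0.43), Mx1 (3.01 ± 0.27) and Gbp3 (2.07 ± 0.36). That list's camera adjusted p was 2.80e-05 (adjusted p = 0.471 with an estimated correlation), and its medians were 0.56 and 1.26. Of 24 NF-kB pathway and target genes 4 rose, and 4 adjusted over the list alone, with Icam1 (2.93 ± 0.44), Nfkbie (2.26 ± 0.41) and Tnfrsf1b (1.89 ± 0.34). Their camera adjusted p was 0.00321 (adjusted p = 0.475 with an estimated correlation), with medians of 0.84 and 0.47. Tnf (-0.07 ± 0.50) and Nfkbia (-0.20 ± 0.23) did not pass. Of 16 MHC class I presentation genes 2 rose, or 3 adjusted over the list alone, H2-M3 (2.28 ± 0.32) and B2m (1.28 ± 0.23), with a camera adjusted p of 0.0305 (adjusted p = 0.491 with an estimated correlation) and medians of 0.71 and 0.52. Without GM-MPP 1, GM-DC 2 or GM-TNFa-DC 1 that call was lost (adjusted p = 0.0753, 0.0805 and 0.0527). Of 21 JAK-STAT-SOCS genes Stat2 rose (1.48 ± 0.25), or 4 higher and 1 lower adjusted over the list alone, with a camera adjusted p of 0.0198 (adjusted p = 0.601 with an estimated correlation, and 0.271 without GM-DC 1) and medians of 0.79 and 0.08.

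Cytokine receptors moved both ways. Of 28, 5 rose and 3 fell, or 9 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.134). Il7r, the interleukin-7 receptor, rose by 5.56 ± 0.27, Csf2rb2, a cytokine receptor subunit, rose by 2.94 ± 0.19, and Il1r2, a decoy receptor for interleukin-1, changed by -3.26 ± 0.33. Csf2ra (1.10 ± 0.28, adjusted p = 0.0912) and Csf1r (2.36 ± 0.76, adjusted p = 0.153) did not pass. Of 15 immediate early and heat shock genes 3 rose, or 4 higher and 2 lower adjusted over the list alone, with Egr2 (5.57 ± 0.56), Atf3 (3.57 ± 0.26) and Hspa1b (2.01 ± 0.29), and the list was not called (camera adjusted p = 0.301).

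Markers of other cell types were measured alongside. Of 25 monocyte and macrophage markers 5 rose, or 8 higher and 4 lower adjusted over the list alone, with Cd36, Axl (5.69 ± 0.42) and Ctsk (5.13 ± 0.43). The list's camera adjusted p was 0.00668 (adjusted p = 0.491 with an estimated correlation, and 0.0577 without GM-MPP 1), and its medians were 1.46 and 1.23. Of 14 mast cell, basophil and eosinophil markers 2 fell, or 5 adjusted over the list alone, Mcpt8 (-3.08 ± 0.37) and Ms4a2 (-2.93 ± 0.35), and the list was not called (camera adjusted p = 0.0787). Of 16 erythroid and megakaryocyte markers 3 fell, or 5 adjusted over the list alone, among them Itga2b (-2.12 ± 0.31) and Car1 (-1.74 ± 0.13), with a camera adjusted p of 0.0205 (adjusted p = 0.465 with an estimated correlation) and medians of -0.36 and -0.21. That call was lost without GM-DC 1 (adjusted p = 0.0804) and without dim genes (adjusted p = 0.156). Of 14 lymphoid markers Cd79b fell (-1.51 ± 0.21), or 2 adjusted over the list alone, with a camera adjusted p of 0.605. No member of the plasmacytoid dendritic cell or the stromal and endothelial list passed, over all genes or adjusted over the list alone (camera adjusted p = 0.782 and 0.736).

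With the array number as a block, 627 genes were higher and 849 lower in GM-DC, and 338 and 477 of the genes called without it were called again. Camera called all 18 lists again. On both numbers alike, 664 genes were at least 2-fold higher and 741 at least 2-fold lower, while 40 went 2-fold or more in opposite directions. The counts rested on all 4 arrays: they fell to 26 and 57 without GM-MPP 1, 20 and 30 without GM-MPP 2, 61 and 67 without GM-DC 1, and 88 and 73 without GM-DC 2, where the lone array was assumed to vary like the other groups. Leaving out GM-DC 1 also brought the mast cell, basophil and eosinophil list past the threshold (adjusted p = 0.0310). The 3' minus 5' log2 difference of the control probe sets for Tfrc was 1.761 and 1.976 on the GM-MPP arrays and 1.233 and 1.244 on the GM-DC arrays. On the GM-DC arrays its 5' probe set lay at 3.341 and 3.482, near the lower quartiles of 3.408 and 3.436. The difference is compressed there, so it does not compare RNA quality between these groups. Of the 63 named genes that passed, 12 passed without GM-MPP 1, 11 without GM-MPP 2, 27 without GM-DC 1 and 29 without GM-DC 2.

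**Figure D2:**
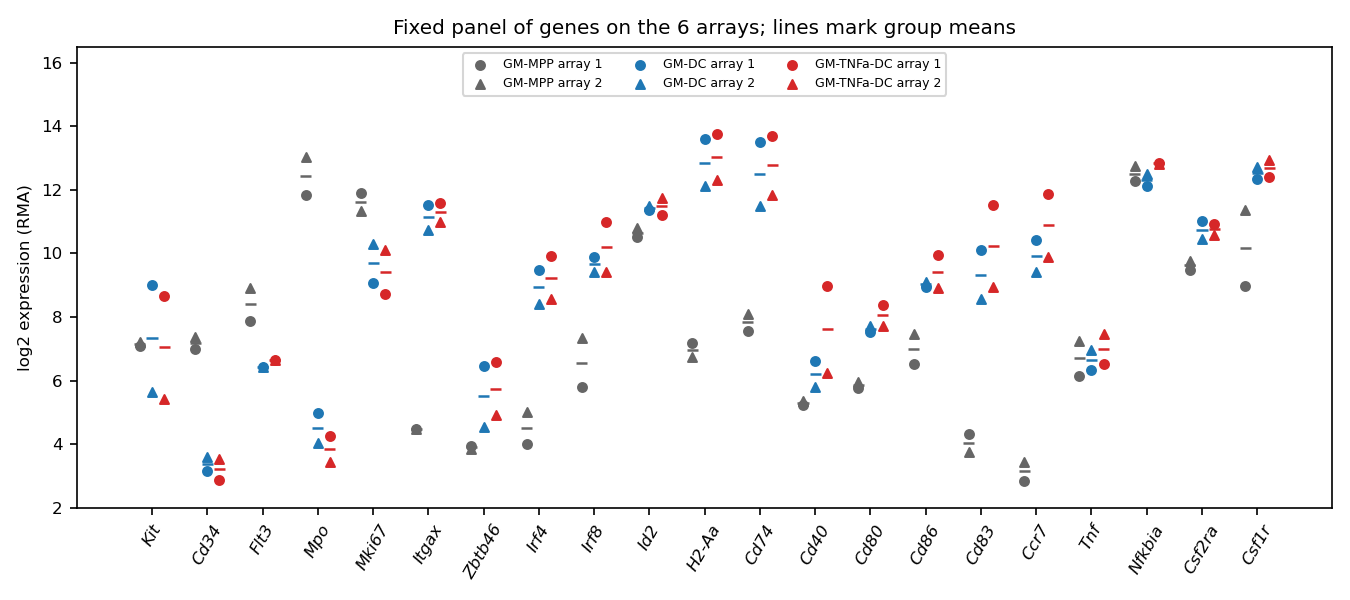
Log2 expression (y axis) of the fixed panel of genes (x axis) on each of the 6 arrays. Circles and triangles are arrays 1 and 2, and short lines are the group means of 2 arrays. Itgax, H2-Aa and Ccr7 lie higher and Mpo and Cd34 lower on every dendritic cell array than on both GM-MPP arrays, while Kit is split by array number.

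The comparison of GM-TNFa-DC with GM-DC addresses what adding TNFa changed. Genes of the NF-kB pathway, through which TNFa acts on transcription, were higher as a group, but no single gene passed. All 24 measured members had a mean above that in GM-DC, 22 were higher on both numbers, and the median log2 change was 0.81, with 1.06 on number 1 and 0.48 on number 2. Values were 1.44 ± 0.57 for Bcl3, 1.40 ± 0.65 for Nfkbiz, 1.28 ± 0.61 for the subunit gene Nfkb2 and 0.52 ± 0.23 for Nfkbia, which encodes an inhibitor of NF-kB. The list was called by camera (adjusted p = 1.22e-12, and 6.20e-14 with the array number as a block). The call was lost with an adjusted p = 0.351 with an estimated correlation, and with fry, which tests the list alone (adjusted p = 0.0867). Over all genes 0 were higher and 0 lower (limma, lowest adjusted p = 1), also with the block, against 270 and 140 at an unadjusted p under 0.05, or 366 and 226 with the block. Both totals are below the share of 0.05 of the 18193 genes that unchanged groups would give on average. Same-numbered dendritic cell arrays deviate together (correlation 0.806), which GM-MPP hardly shares (0.105 and 0.0719). Both fits count this at least partly as spread and so are conservative here. The 0 calls thus do not show that nothing changed. The block on only the 4 dendritic cell arrays takes out that shared deviation, and it also called 0 and 0. It has only 1 residual degree of freedom, so smaller changes can be missed. The same fit did call 1166 genes higher and 984 lower on number 2. On both numbers alike, 13 genes were at least 2-fold higher and 9 at least 2-fold lower. For every list in this comparison, 0 members passed adjusted over the list alone.

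Dendritic cell maturation genes had a median of 0.55, with 0.91 on number 1 and 0.26 on number 2, and 20 of 24 were higher on both. Ccl22 differed by 1.36 ± 0.53, Icam1 by 1.21 ± 0.44, Cd40 by 1.40 ± 0.87, Ccr7 by 0.98 ± 0.70, Cd83 by 0.90 ± 0.93, Cd80 by 0.43 ± 0.28 and Cd86 by 0.40 ± 0.46, none of which passed. The camera adjusted p was 4.38e-06, with adjusted p = 0.465 with an estimated correlation and 0.199 by fry. Without GM-TNFa-DC 1 the call was lost (adjusted p = 0.293). Chemokines and cytokines (median 0.39, with 0.31 and 0.32 on the numbers, camera adjusted p = 0.00646, adjusted p = 0.551 with an estimated correlation) included Tgfb1 at 0.50 ± 0.19, of which only 1 of 2 probe sets was higher. The call of chemokines and cytokines was lost without GM-TNFa-DC 2 (adjusted p = 0.770), and without GM-DC 1 the direction turned (adjusted p = 0.548). MHC class I presentation genes had a median of 0.28 (0.51 and 0.15, camera adjusted p = 0.00860, adjusted p = 0.468 with an estimated correlation), with Tapbpl at 0.58 ± 0.25. Tap1 was at 0.74 ± 0.35, with 2 of its 4 probe sets higher. Without GM-DC 1, GM-TNFa-DC 1 or GM-TNFa-DC 2 the class I call was lost (adjusted p = 0.426, 0.0579 and 0.0836). Interferon-stimulated genes had a median of 0.30 (0.44 and 0.17, camera adjusted p = 0.0478, adjusted p = 0.624 with an estimated correlation), with Gbp2 at 0.98 ± 0.43. Their direction turned without GM-DC 1 and without GM-TNFa-DC 2 (adjusted p = 0.185 and 0.747), and with the mean of a gene's probe sets the call was lost (adjusted p = 0.0532). The block kept the calls of all 11 lists called in this comparison.

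Lists that camera called lower were neutrophil granule and lineage genes, with a median of -0.56 (-0.98 on number 1 and -0.04 on number 2, adjusted p = 7.16e-05, adjusted p = 0.465 with an estimated correlation), and cell cycle genes, at -0.45 (-0.36 and -0.48, adjusted p = 3.70e-04, adjusted p = 0.631 with an estimated correlation). Of 29 cell cycle genes 26 were lower on both numbers, with Mki67 at -0.27 ± 0.60. Lysosome genes (median -0.17, adjusted p = 0.00365, adjusted p = 0.465 with an estimated correlation), ribosome biogenesis genes (-0.15, adjusted p = 0.0205, adjusted p = 0.631 with an estimated correlation), pattern recognition and uptake receptors (-0.16, adjusted p = 0.0332, adjusted p = 0.637 with an estimated correlation) and monocyte and macrophage markers (-0.22, adjusted p = 0.0369, adjusted p = 0.597 with an estimated correlation) shifted less. Their medians on numbers 1 and 2 were -0.23 and -0.06, -0.15 and -0.11, -0.47 and -0.03, and -0.17 and -0.15. Of these 6 lists none stayed called whichever array was left out. The direction turned without GM-DC 2 and without GM-TNFa-DC 1 for cell cycle genes (adjusted p = 0.0597 and 0.314) and pattern recognition receptors (0.883 and 0.248), and without GM-DC 1 and without GM-TNFa-DC 2 for ribosome biogenesis genes (0.426 and 0.657). The call was lost without GM-DC 1 for neutrophil genes (adjusted p = 0.242), and without GM-DC 2 or GM-TNFa-DC 1 for lysosome genes (0.237 and 0.314) and monocyte and macrophage markers (0.776 and 0.796). With the arrays quantile-normalized again, ribosome biogenesis genes and pattern recognition receptors had adjusted p = 0.0584 and 0.0519, and without dim genes the pattern recognition receptors and the monocyte and macrophage markers had 0.0904 and 0.0692. The MHC class II list was not called (median 0.17, adjusted p = 0.456, turned and at 0.0361 without GM-TNFa-DC 1), with H2-Aa at 0.17 ± 0.65, nor were dendritic cell identity genes (0.23, adjusted p = 0.0838), with Itgax at 0.16 ± 0.34. The other 12 lists had camera adjusted p between 0.0693 and 0.991.

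Of the 14 lists not called between the dendritic cell groups, 4 were called under another filter, probe set rule or choice of arrays in the fit, and 8 when an array was left out. Leaving out a dendritic cell array sets unequal array numbers against each other. A call gained that way cannot be told apart from the split by number. MHC class II genes, for example, differed between numbers 2 and 1 by a median of -1.30 in GM-DC and -1.59 in GM-TNFa-DC. Without dim genes, adjusted p was 0.0132 for dendritic cell identity genes, 0.0213 for transcription factors of dendritic cell development and 0.0411 for immediate early and heat shock genes. Cholesterol synthesis genes had 0.0269 with the mean of a gene's probe sets and also with only the 4 arrays compared, 0.0278 without GM-MPP 1, 0.0265 without GM-MPP 2, 0.00788 without GM-DC 2 and 0.0107 without GM-TNFa-DC 1. Without GM-DC 1, adjusted p was 0.00158 for dendritic cell identity genes, 5.95e-04 for MHC class II genes and 0.00148 for JAK-STAT-SOCS genes. Without GM-TNFa-DC 2 it was 5.76e-05, 5.14e-04 and 7.60e-04 for these lists and 0.00110 for the transcription factors. Without GM-DC 2 it was 0.0124 for glycolysis genes and 0.0331 for plasmacytoid dendritic cell markers, and without GM-TNFa-DC 1 it was 0.00760 for glycolysis genes and 0.0103 for stem and progenitor genes.

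The largest single differences without overlap between the 4 arrays did not pass either. Fst, which encodes the activin antagonist follistatin, was higher by 3.31 ± 0.80 (4.77 on number 1 and 1.85 on number 2), the complement gene Cfb by 2.59 ± 1.22, the lectin receptor Clec4e by 2.38 ± 0.89, Slamf8 by 1.91 ± 0.47, Asb11 by 1.65 ± 0.49 and Orm1 by 1.60 ± 0.47. Klk1b11 differed by -1.71 ± 0.57, the lectins Mgl2 by -1.58 ± 0.78 and Clec10a by -1.43 ± 0.61, Frmd4b by -1.54 ± 0.52, Gask1b by -1.43 ± 0.65, and Slc9a9 by -1.45 ± 0.57, with 2 of its 4 probe sets lower. The chemokine receptor Ccr2 was at -1.35 ± 0.66 (-1.26 and -1.44 on the numbers) and Junb at 0.99 ± 0.40 (1.01 and 0.97). The rule on overlap leaves out genes that differ strongly between array numbers. One of them, Il1b, added after seeing the data, was higher by 2.31 ± 1.34 (2.308 and 2.314 on the numbers). All had an adjusted p of 1. Simulated arrays with the spread of these data, without a batch, gave calls for 34% of genes changed 2-fold and 86% of genes changed 4-fold in this comparison. Other simulated genes were moved 16-fold or 64-fold, which eased the adjusted threshold. Here no gene was called, so these shares do not say how many genes changed 2-fold or 4-fold would be called.

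**Figure D3:**
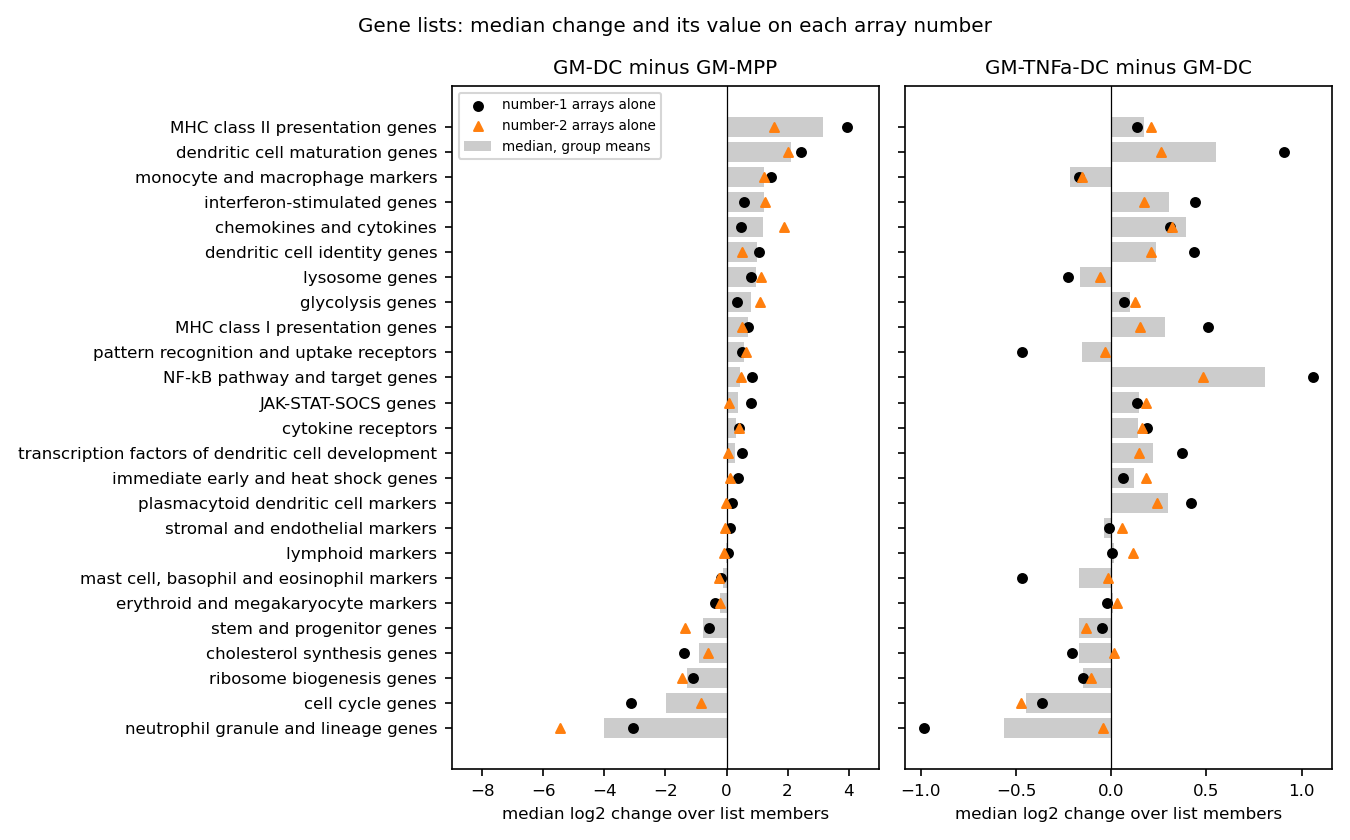
Median log2 change over the members of 25 gene lists (x axis) in GM-DC minus GM-MPP and in GM-TNFa-DC minus GM-DC. Bars are medians of the differences between group means, and circles and triangles are the medians within arrays 1 and 2 alone. In the second panel the NF-kB list has the longest bar, at 0.81, with 1.06 on number 1 and 0.48 on number 2.

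The comparison of GM-TNFa-DC with GM-MPP gave 504 genes higher and 775 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Mmp12 (log2 change 9.56 ± 0.35), Ccl17 (7.77 ± 0.42), Ccr7 (7.74 ± 0.70), Ccl5 (7.54 ± 0.72), Fscn1 (7.44 ± 1.14) and Procr, the protein C receptor (7.11 ± 1.23), rose most, and Mpo (-8.60 ± 0.55), Ctsg (-7.90 ± 0.55), Ms4a3 (-7.39 ± 0.50), Prtn3 (-6.88 ± 0.40), Myb (-6.81 ± 0.52) and Elane (-6.75 ± 0.31) fell most. Of 24 maturation genes 13 rose, or 20 adjusted over the list alone, with Cd80 at 2.20 ± 0.28, Cd86 at 2.43 ± 0.46 and Cd83 at 6.18 ± 0.93. Their median was 2.66 (3.47 and 2.42 on the numbers, camera adjusted p = 1.17e-12, adjusted p = 0.351 with an estimated correlation). Of 24 NF-kB genes 7 rose, or 11 adjusted over the list alone, led by Icam1 (4.14 ± 0.44) and Nfkbie (3.42 ± 0.41), with a median of 1.43 (1.65 and 1.07, camera adjusted p = 7.29e-08, adjusted p = 0.458 with an estimated correlation). Socs1 (2.04 ± 0.34) and Socs3 (1.99 ± 0.39), feedback inhibitors of cytokine signalling, and Irf8 (3.65 ± 0.69) also rose. Whether these changes differed from those in GM-DC is what the comparison of the dendritic cell groups tested, and no gene passed it.

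Of 20 ribosome biogenesis genes 9 fell in GM-TNFa-DC against GM-MPP, or 18 adjusted over the list alone, with Dkc1 at -3.80 ± 0.37. Their median was -1.35 (-1.18 and -1.64, camera adjusted p = 2.06e-12, adjusted p = 0.465 with an estimated correlation). Of 29 cell cycle genes 3 fell, or 25 adjusted over the list alone, the helicase genes Mcm6 (-2.96 ± 0.61), Mcm7 (-2.73 ± 0.43) and Mcm2 (-2.61 ± 0.48). Their median was -2.42 (-3.38 and -1.31, camera adjusted p = 6.42e-12, adjusted p = 0.491 with an estimated correlation). Of 14 MHC class II genes 6 rose, or 11 adjusted over the list alone, with H2-Eb1 at 6.12 ± 1.07 and H2-Aa at 6.06 ± 0.65, and a median of 3.08 (3.88 and 1.497, camera adjusted p = 1.03e-07, adjusted p = 0.465 with an estimated correlation). The lymphoid marker Ighm was at -4.66 ± 0.96 (adjusted p = 0.0489), with 9 of its 11 probe sets lower. In this comparison camera called 16 of the 25 lists. The block kept all but the erythroid and megakaryocyte markers (adjusted p = 0.0205, and 0.0509 with the block), whose call was also lost without GM-TNFa-DC 1 (adjusted p = 0.0665) and without dim genes (0.237). Without GM-TNFa-DC 1 the JAK-STAT-SOCS list was lost as well (adjusted p = 0.0140 with all arrays and 0.314 without it). Of the 9 lists not called, 4 were called under another scaling or filter. Pattern recognition receptors had adjusted p = 0.0359 with the arrays quantile-normalized again, 0.0225 with median centring, 0.0314 without dim genes, 0.0413 without GM-MPP 2 and 7.72e-04 without GM-TNFa-DC 1. Monocyte and macrophage markers had 0.0487, 0.0225, 0.0308, 0.0171 and 0.0143 in the same order. Transcription factors of dendritic cell development had 0.0483 without dim genes and 0.0202 without GM-TNFa-DC 2, and mast cell, basophil and eosinophil markers had 0.0411 without dim genes.

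With the array number as a block, 850 genes were higher and 1210 lower in GM-TNFa-DC than in GM-MPP, with 501 and 772 called both ways. On both numbers alike, 691 were at least 2-fold higher and 967 at least 2-fold lower. Counts fell to 37 and 76 without GM-MPP 1, 40 and 51 without GM-MPP 2, 131 and 134 without GM-TNFa-DC 1, 287 and 296 without GM-TNFa-DC 2, 303 and 457 without GM-DC 1, and 303 and 457 without GM-DC 2.

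Both dendritic cell groups were set against the same GM-MPP arrays. Of the genes called, 312 were higher and 459 lower in both, and 0 were called in opposite directions. Independent lists of these sizes would share 9.42 and 20.4 genes. In 100 simulations of unchanged groups sharing the GM-MPP arrays the overlap was 0, but unchanged groups give hardly any calls, so this sets no chance value for lists of these sizes. Across genes the log2 changes correlated at 0.957, against a mean of 0.499 in the simulations, and their covariance was 0.705 against 0.0563. Those simulations leave out that same-numbered arrays of the dendritic cell groups deviate together. With that included, the simulated correlation was 0.904 and the covariance 0.102. With GM-DC set against GM-MPP 1 and GM-TNFa-DC against GM-MPP 2, a division chosen after seeing the data, the correlation was 0.875 and the covariance 0.674, and with the GM-MPP arrays exchanged they were 0.853 and 0.662. This takes out the shared GM-MPP arrays but not the deviations shared by array number. The calls could not be divided this way with 2 GM-MPP arrays in each comparison, so part of the excess of shared calls over independent lists may come from the shared arrays. Without GM-MPP 1 the genes called in both numbered 25 and 55, without GM-MPP 2 they numbered 20 and 30, without GM-DC 1 they numbered 60 and 67, without GM-DC 2 they numbered 83 and 72, without GM-TNFa-DC 1 they numbered 127 and 124, and without GM-TNFa-DC 2 they numbered 196 and 234. With the block they numbered 557 and 797.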

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

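The values within each array number, the block on 4 arrays and the simulations with shared deviations of same-numbered arrays were chosen after the data were seen. Both scalings, the 2-fold minimum, the dim filter (11851 genes kept), probe set means and both other priors left every count of changed genes and every overlap they were run on within 1.5 times. Testing all probe sets gave 519 higher and 732 lower in GM-DC than in GM-MPP and 1251 lower in GM-TNFa-DC than in GM-MPP, from more features tested. With only the 4 arrays of GM-TNFa-DC and GM-MPP, 303 were higher and 446 lower. The same step for GM-DC and GM-MPP gave 349 and 365, against 340 and 479 with all arrays. Fewer degrees of freedom alone thus do not account for the drop, and its cause was not tested. The replicate block gave 627 higher and 849 lower in GM-DC and 850 and 1210 in GM-TNFa-DC than in GM-MPP, and overlaps of 557 and 797. Deviations from the group means correlated across genes at 0.806 for the same-numbered arrays of the dendritic cell groups, but at 0.105 and 0.0719 between GM-MPP and GM-DC or GM-TNFa-DC, and the labels do not say what a number shares, so the block is not part of the main model. Leaving out 1 array gave 20 to 346 higher and 30 to 371 lower in GM-DC, 37 to 303 and 51 to 457 in GM-TNFa-DC than in GM-MPP, and overlaps of 20 to 196 and 30 to 234. Between the dendritic cell groups every alternative run, including the block on 4 arrays, gave 0 and 0.

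The NF-kB list of GM-TNFa-DC against GM-DC had adjusted p = 0.351 with an estimated correlation and 0.0867 by fry, and stayed called whichever array was left out, at 4.00e-13 to 3.43e-05. The maturation list had 0.465 and 0.199, and 2.73e-10 to 0.293 without 1 array. In that comparison other lists turned direction when 1 array was left out, which sets unequal array numbers against each other. Their adjusted p then ranged from 4.77e-18 to 0.314 for cell cycle, 2.33e-05 to 0.657 for ribosome biogenesis, 5.14e-04 to 0.542 for MHC class II, 4.07e-06 to 0.770 for chemokines and cytokines, 1.97e-05 to 0.747 for interferon-stimulated genes, and 8.72e-07 to 0.883 for pattern recognition receptors. The turned values were 0.0597 and 0.314 for cell cycle, 0.426 and 0.657 for ribosome biogenesis, 0.0361 for MHC class II, 0.548 for chemokines, 0.185 and 0.747 for interferon-stimulated genes, and 0.883 and 0.248 for pattern recognition receptors. Except where a reason is given, the cause was not tested. The block kept 18 of 18, 11 of 11 and 15 of 16 list calls, and 13 of 18, 1 of 11 and 14 of 16 stayed called whichever array was left out. Of the lists not called, 1 of 7, 8 of 14 and 3 of 9 were called when an array was left out, and 0, 4 and 4 under another scaling, filter, probe set rule, prior or choice of arrays. Of the named genes called, 63 of 63 and 72 of 72 were called with the block, and 10 of 63 and 13 of 72 whichever array was left out. Without a detection call, the signal over background of dim genes limits their fold changes.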

Other observations

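All tests in this part were chosen after the result was seen, and so were the genes named here outside the lists. Within both dendritic cell groups the number-1 and number-2 arrays correlated less with each other than each did with the same-numbered array of the other group. At least 4-fold the same way in both groups, 161 genes were higher and 91 lower on number 2, and 0 went in opposite directions. Arg1, which encodes arginase-1, was higher on number 2 by 9.67 on the log2 scale in GM-DC and 9.67 in GM-TNFa-DC, the matrix gene Fn1 by 5.71 and 6.53, Thbs1 by 6.17 and 7.27, and the chemokine gene Cxcl3 by 8.08 and 4.79. Cd209a, a lectin of dendritic cells, differed by -7.05 and -4.46, Fbp1 by -5.95 and -4.45, and H2-DMb2 by -3.71 and -4.46. Over the 4 dendritic cell arrays, with group and number in the model, limma called 1166 genes higher and 984 lower on number 2 (Benjamini-Hochberg adjusted p under 0.05, 1 residual degree of freedom). These p-values measure a shift shared by both groups against what is left between them, not the spread between independent cultures, and the genes named here were picked on the same arrays, so it is no test of them.

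The fixed lists split in several directions. Cell cycle genes were higher on number 2 by a median of 1.53 in GM-DC and 1.42 in GM-TNFa-DC, against -0.499 in GM-MPP, with 21 of 29 at least 2-fold higher in both dendritic cell groups. Interferon-stimulated genes were higher by 1.42 and 1.37, and by 0.431 in GM-MPP, with 14 of 25 at least 2-fold higher in both dendritic cell groups. MHC class II genes were lower, by -1.30 and -1.59, against 0.286 in GM-MPP, with 7 of 14 at least 2-fold lower. Dendritic cell identity genes differed by -0.690 and -0.979, against 0.115 in GM-MPP.

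For this split between array numbers, a labelling batch shared by all groups may contribute, since the poly-A controls differ in all 3. As the whole source it is argued against by the genes 4-fold apart, of which 170 lay above the array median in GM-MPP. There they differed in the dendritic cell direction by a median of 0.324 (95% bootstrap interval over genes 0.122 to 0.461), against 2.77 in the dendritic cells. Picking genes at 4-fold or more made the dendritic cell value large in advance, which widens this gap. The interval rests on 1 pair of GM-MPP arrays and does not measure the spread between arrays. RNA degradation stays open: the 3' minus 5' values of Gapdh and Actb differed by at most 0.162 between numbers within the dendritic cell groups, but these probe sets were brighter than at least 99.8% of those on their array, where differences are compressed. The dimmer Pcx control was at -0.311 and 0.153 in GM-DC and at 0.075 and 0.379 in GM-TNFa-DC. Tfrc, also dim, differed little, at 1.233 and 1.244 in GM-DC and 1.051 and 1.137 in GM-TNFa-DC, but its 5' probe set lay near the lower quartile of these arrays. A larger share of monocytes or macrophages on number 2 stays open: 9 of 25 markers were at least 2-fold higher there in both groups, such as Cd14 by 5.02 and 4.68 and Itgam by 4.56 and 3.63, but Mrc1 was lower, by -3.36 and -3.49, as were, by less than 2-fold in at least 1 group, Mertk (-0.86 and -1.03), Axl (-1.005 and -0.61), Ctsk (-0.90 and -0.78), Marco (-0.81 and -0.63), Cd163 (-0.54 and -0.15) and Ccr2 (-0.080 and -0.26), so that 1 marker was at least 2-fold lower in both, and the abundant Lyz2 differed by 0.0111 and 0.190, from a level too high to show a small share. Cd14 and Mrc1 are also in the list of pattern recognition and uptake receptors, and in GM-MPP the marker list was higher on number 2 too, by a median of 0.949, against 0.397 and 0.595. The labels name no difference between the numbers, so beyond this cell share no biological explanation was tested.

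The NF-kB list differed less between GM-TNFa-DC and GM-DC on number 2 than on number 1, by a median of 0.406 (95% bootstrap interval over genes 0.162 to 0.598), with 19 of 24 members differing more on number 1. A labelling batch that stretches all changes on number 1 stays open. The SD over genes of the GM-DC minus GM-MPP change was 1.12 times as large there (interval 1.09 to 1.15). That is another comparison, so it does not decide. In GM-TNFa-DC against GM-DC most other called lists also had larger medians on number 1, such as maturation genes (0.91 and 0.26) and neutrophil genes (-0.98 and -0.04). Cell cycle genes (-0.36 and -0.48) and chemokines and cytokines (0.31 and 0.32) did not. The hypothesis that GM-DC 2 already had higher NF-kB targets stays open: the list's median difference between GM-DC 2 and GM-DC 1 was 0.0357, with an interval of -0.254 to 0.368 that covers both 0 and the 0.203 that the explanation required at the least. GM-TNFa-DC 2 was lower than GM-TNFa-DC 1 by a median of -0.301 (interval -0.688 to -0.0112). Each value rests on single arrays, and the labels name no difference between the numbers to test.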
